A study of Homo sapiens with 6 samples.

How the data were processed

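The series measured RNA from IMR90 human fetal lung fibroblasts in 6 libraries, 3 with a hairpin against luciferase and 3 with a hairpin against macroH2A1. Per the labels' protocols, total RNA was depleted of ribosomal RNA, the second cDNA strand was made with dUTP and later treated with uracil N-glycosylase, so that libraries keep strand, and all libraries ran in a single sequencing lane. Lane and sequencing run are therefore shared by both groups. Groups and replicate numbers were taken from the sample titles.

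The authors deposited raw read counts per Ensembl gene for each library, made per the submitters' processing notes with CASAVA 1.7, GSNAP (whose version the notes give as a date) and HTSeq on the genome build hg19; the names of the deposited files say union mode. The gene annotation, the HTSeq version and its strand setting are not given in the sources used here, so values of genes that overlap on opposite strands are uncertain. HTSeq in this mode leaves out reads that align to several places, which lowers the counts of genes with near-identical copies. Lines of the deposited count files that name no gene were left out of library sizes and tests: 64.4% to 68.8% of the reads listed had no unique alignment, 6.85% to 9.63% were not aligned, 8.34% to 11.3% fell outside annotated features, 1.51% to 1.85% were ambiguous and 0.326% to 0.479% were of low quality. Reads assigned to genes made up 11.9% to 13.7%.

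The authors also deposited a table of the comparison, made with DESeq 1.10.1 per the submitters' processing notes. Its columns, per the file headers, hold a mean signal over all samples (counts divided by size factors), the ratio of the group means, the log2 of that ratio, a p-value and an adjusted p-value. By its name, the authors' table holds protein-coding genes, and the lowest count sum among them was 21. Its 11636 finite log2 ratios lie within 0.0029 of the log2 ratio of group means, knockdown over control, computed here from the deposited counts with DESeq2 size factors.

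Depth ranged from 3741087 to 6421605 gene counts per library, where 3 counts correspond to 0.467 to 0.802 counts per 1000000. The 20 most abundant genes took 29.1% to 34.0% of the gene counts. Libraries of 1 group differed by more than sampling noise, with a chi-square of 25.2 to 37.7 per degree of freedom over genes with at least 20 counts in a pair, so none was counted as a copy of another. The biological coefficient of variation was 24.9%.

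Tests were run with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3. The 57659 genes of the files were filtered with filterByExpr (minimum count 10) by group, scaled with TMM and tested with glmQLFit and glmQLFTest, with group as the only term and a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM values are counts per 1000000 over TMM-scaled library sizes. For named genes with at most 10 counts in a group, ratios of summed counts have exact conditional 95% intervals, and a group at 0 is set to a floor of 3 counts over the group.

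Gene symbols, types, chromosome, order, GC content and transcript length came from GENCODE 29 by Ensembl identifier, which matched 47399 genes. That annotation is on another build than hg19, so no coordinates are given. Before the data were examined, the main tests, most alternatives, 24 gene lists and the rule for named genes were fixed. The rule named MACROH2A1 and MACROH2A2, then the 10 called genes of largest fold change in each direction with groups that do not overlap and a mean log2 CPM of at least 1, leaving out clone names, XIST and Y-linked genes, then up to 4 genes of lowest p per list. Other genes named within a list are called members of it, chosen after their values were seen. Some genes that the rule picked are not reported here. Of 794 list entries, 36 had no match, 33 of them replication-dependent histones.

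Lists were tested with camera at a preset correlation of 0.01 and adjusted over the 24 lists; an estimated correlation, fry and cameraPR were alternatives. Other alternatives were 3 other scalings, leaving out the 20 most abundant genes, 2 other filters, the genes of the authors' table only, a replicate block, leaving out each library, DESeq2, limma-voom and other thresholds. A robust prior and an offset for GC content and length were added after seeing the data. The steps were tested on simulated counts for the real genes, with 200 genes changed and a list of 40 others raised by 0.5 on the log2 scale. In the simulated comparison of knockdown with control, 13153 genes were run. Among the 200, edgeR recovered 1.49% of changes of 0.5 on the log2 scale, 31.3% of changes of 1 and 92.4% of changes of 2. Of its 94 calls, 10 were of unchanged genes and so false. Fewer genes changed there than were called in the data, so these shares need not hold for the data.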

Results

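RNA was sequenced from IMR90 cells, a widely used line of primary human fetal lung fibroblasts, that expressed a short hairpin RNA directed either at macroH2A1 or at luciferase, a firefly gene that human cells lack and that serves as the control. MacroH2A1 is a variant of histone H2A with a large globular domain joined to its tail. The design holds 2 groups of 3 libraries, which the series calls biological replicates, and 1 comparison: which genes change when macroH2A1 is depleted. The 3 control libraries held 6421605, 4417869 and 3744716 reads assigned to genes, and the 3 knockdown libraries held 5322851, 4505853 and 3741087.

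The targeted gene was lower in every knockdown library. MACROH2A1 (older symbol H2AFY, ENSG00000113648, chromosome 5) had 582, 385 and 321 counts in the control libraries and 197, 201 and 149 in the knockdown libraries. Its normalized count fell from 88.3 ± 3.62 to 40.9 ± 2.51 counts per 1000000 (CPM; SD, n = 3 per group), which leaves 46.3% of the control level (log2 fold change -1.11, SE 0.08, edgeR adjusted p = 0.000917). As a share of all gene counts, the lowest control library had 85.7 counts per 1000000 (exact 95% binomial interval 76.6 to 95.6) and the highest knockdown library 44.6 (38.7 to 51.2); these intervals cover counting error only. MACROH2A2, the gene of the related variant macroH2A2, went from 8.19 ± 0.587 to 12.5 ± 2.60 CPM (n = 3 per group), a log2 fold change of 0.60 (SE 0.20) that did not pass the test (edgeR adjusted p = 0.116).

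**Figure D1:**
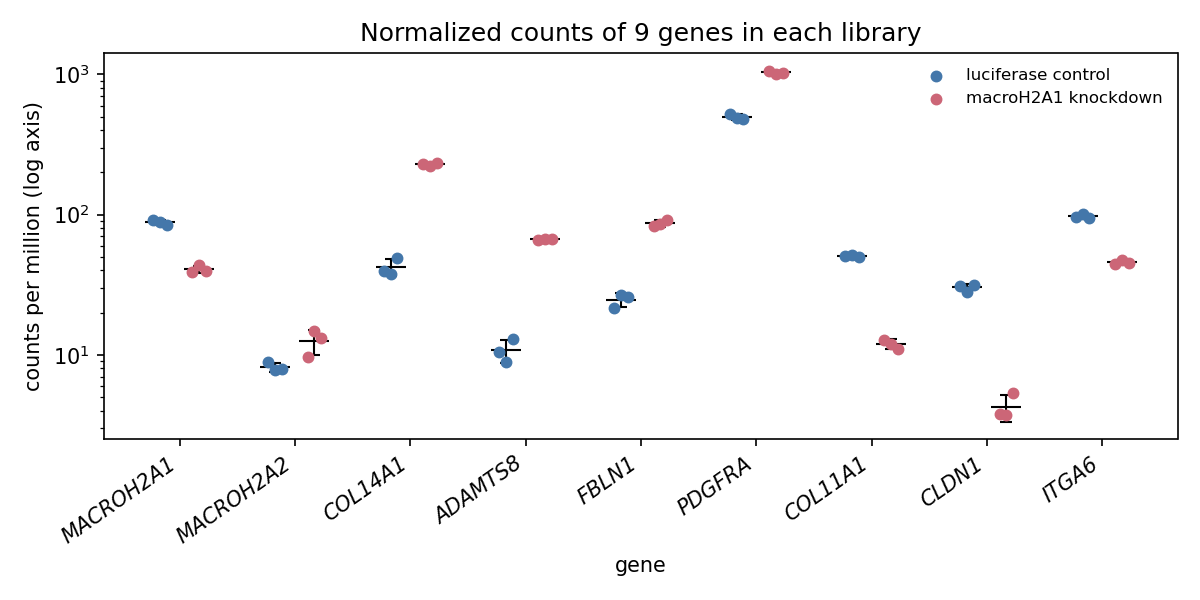
Counts per 1000000 on a log axis for 9 genes in each of the 6 libraries; coloured points are libraries, black dashes are group means and bars are 1 SD (n = 3 per group). MACROH2A1 lies at 88.3 CPM on average in the control and at 40.9 in the knockdown, and the groups of every gene shown stay apart.

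Depletion of macroH2A1 went with changes in both directions. Of 13445 genes tested, 524 were higher and 580 lower in the knockdown (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 178 of the higher and 93 of the lower genes differed by at least 2-fold. Among protein-coding genes, 459 rose and 547 fell of 10437 tested. The largest increases of protein-coding genes that the rule for named genes picked were those of TMEM176B, a membrane protein, KDR, a receptor for vascular endothelial growth factor, A2M, a secreted protease inhibitor, SHISA3, FMO2, a flavin-containing monooxygenase, PDE3A, a cyclic nucleotide phosphodiesterase, and BTN1A1. The largest decreases of protein-coding genes were those of HDAC9, a histone deacetylase, and SERPINB7.

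TMEM176B had no counts in any control library and 82 in the knockdown libraries together, so it was at least 29.6-fold higher against a floor of 3 counts over the control group. KDR had 5 counts in the control group and 111 in the knockdown group, a 24-fold ratio with an exact 95% counting interval of 9.99 to 75.4. SHISA3 rose 8.70-fold from 2.40 ± 0.700 CPM (n = 3 per group, edgeR adjusted p = 0.000844), FMO2 8.67-fold and PDE3A 6.57-fold. A2M had 8 control and 68 knockdown counts, a 9.19-fold ratio with a counting interval of 4.41 to 22.1. HDAC9 went the other way, with 121 control and 6 knockdown counts, 18.6-fold lower with an interval of 8.32 to 51.8, and SERPINB7, with 99 and 10 counts, was 9.15-fold lower with an interval of 4.77 to 19.7. BTN1A1 and SERPINB7 each lost their call in 7 of 18 alternative settings, and HDAC9 in 4.

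The same rule also named short RNAs of multi-copy families, whose reads can fall on near-identical copies, so their values are uncertain. The small nucleolar RNAs SNORA15B-2 and SNORD32B and a Y RNA were higher, by 8.38-fold, 6.83-fold and 7.32-fold. SNORA15B-2 had 1, 15 and 3 control counts and lost its call in 9 of 17 alternative settings, with log2 fold changes from 2.40 to 4.75. Lower were RNU6-61P, a copy of U6, and RNA5SP267, RNA5SP150, RNA5SP145, RNA5SP74, RNA5SP149, RNA5S9 and RNA5-8SP2, copies of 5S and 5.8S ribosomal RNA, with log2 fold changes from -5.14 to -3.17. By gene type, 2 of 4 ribosomal RNA genes and 8 of 17 ribosomal RNA pseudogenes tested were lower and 0 higher. Of 242 small nucleolar RNAs, 15 were higher and 2 lower. The RNA had been depleted of ribosomal RNA, and whether depletion differed between the groups was not tested. RNA5SP267 ranged from 5.02 to 36.1 CPM among the control libraries alone. It and RNA5SP149 each lost their call in 8 of 17 alternative settings, RNA5SP74 and RNA5S9 in 7, and RNU6-61P and RNA5-8SP2 in 6.

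Restricting the rule to protein-coding genes, a choice made after the values were seen, added NSG1, ADAMTS8 and RASL11B among the higher genes and COBLL1, NRXN3, CLDN1, OXTR, ADAMTSL1, RGS4, GDF5 and TMEM178B among the lower. ADAMTS8, a secreted metalloproteinase, rose from 10.8 ± 2.04 to 67.0 ± 0.439 CPM (n = 3 per group, edgeR adjusted p = 0.000566). CLDN1, a protein of tight junctions, fell from 30.3 ± 1.93 to 4.27 ± 0.942 CPM, and OXTR, the oxytocin receptor, from 18.9 ± 0.783 to 2.65 ± 0.850 CPM (n = 3 per group, edgeR adjusted p = 0.000758 and 0.00140). GDF5, a growth factor of the bone morphogenetic protein family, was 5.97-fold lower, and RGS4, a regulator of G protein signalling, 6.76-fold lower. TMEM178B lost its call in 6 of 17 alternative settings, NSG1 in 2 of 17 and ADAMTSL1 in 4 of 18.

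All 1104 called genes had groups whose CPM values did not overlap. With 3 libraries per group a call nearly requires this, so it is no separate support for the calls. Of all genes tested, 30.4% had such groups, against 10% by chance for 3 libraries against 3. The number of calls depended on the libraries and genes used: 436, 427 and 564 genes were called without control replicate 1, 2 and 3, 531, 550 and 517 without knockdown replicate 1, 2 and 3, and 2060 when only genes of the authors' deposited table were tested.

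**Figure D2:**
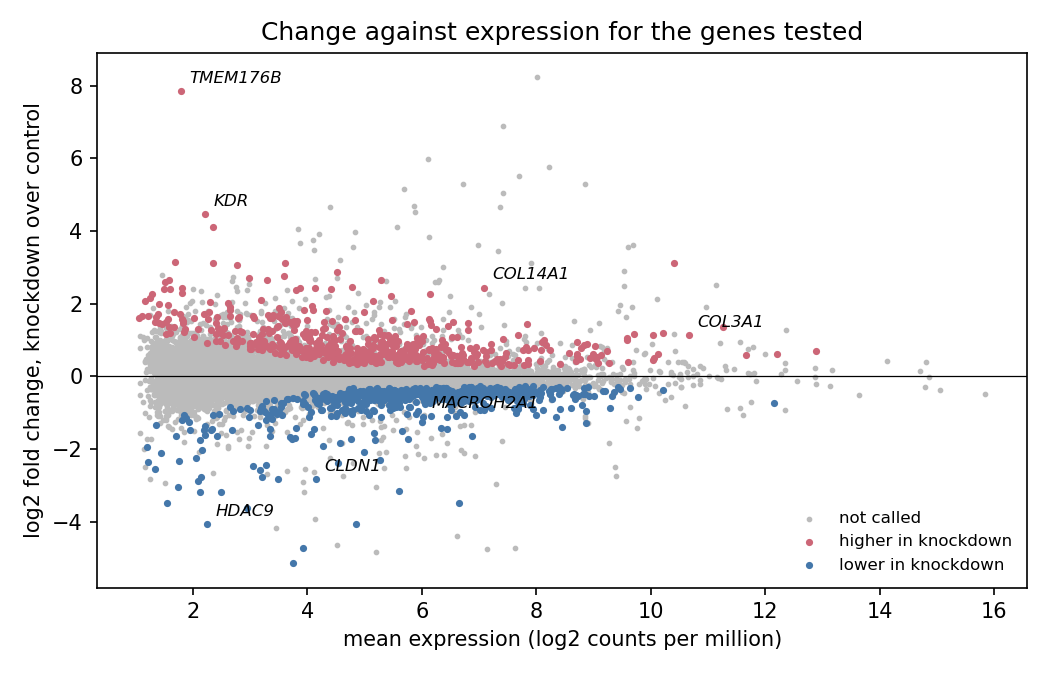
Fitted log2 fold change, knockdown over control, against mean expression in log2 counts per 1000000 for the genes tested, XIST and genes of the Y chromosome left out. Red points rose and blue points fell at an adjusted p under 0.05, and grey points did not pass; MACROH2A1 lies at -1.11, and the fitted value of TMEM176B is no measured fold because its control counts are all 0.

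More genes of the extracellular matrix rose than fell. Of 53 tested members of the list of collagens and matrix genes, 29 rose, 4 fell and 20 did not pass (36 were called when adjusted over the list alone), and 45 had a positive fold change. COL14A1, a fibril-associated collagen, rose from 42.3 ± 6.03 to 230 ± 5.38 CPM, FBLN1, a glycoprotein of elastic fibres and basement membranes, from 24.7 ± 2.81 to 86.5 ± 4.60 CPM, and ADAMTS5, a protease that cleaves aggrecan, from 30.2 ± 3.12 to 85.5 ± 5.33 CPM (n = 3 per group, edgeR adjusted p at most 0.000844). COL3A1, DCN and LUM, which are major products of fibroblasts, rose 2.19-fold, 2.20-fold and 2.04-fold. Against this direction, COL11A1 fell from 50.9 ± 1.12 to 11.9 ± 0.937 CPM, and PLOD2, P4HA1 and LOX, enzymes that modify or cross-link collagen, also fell.

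The matrix list had a median log2 fold change of 0.45 and passed camera with the preset correlation of 0.01 (adjusted p = 9.77e-10), but not with a correlation estimated from the data (adjusted p = 0.261 with an estimated correlation). Fewer members were called in smaller fits: 19, 18 and 27 without control replicate 1, 2 and 3, and 23, 20 and 20 without knockdown replicate 1, 2 and 3, against 33 with all libraries.

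Markers of fibroblasts moved with the matrix genes. Of 16 tested, 6 rose and none fell (11 were called when adjusted over the list alone), among them PDGFRA, the platelet-derived growth factor receptor alpha, at 2.09-fold, and TCF21, a transcription factor of lung mesenchyme, with a log2 fold change of 0.73. The list passed camera (adjusted p = 3.68e-06; adjusted p = 0.151 with an estimated correlation). It shares 5 genes with the matrix list; its other 11 tested genes, a split made after the data were seen, had a median log2 fold change of 0.41 with 2 called (camera p = 0.000785, and p = 0.0244 with an estimated correlation). Among 3 tested endothelial markers, KDR and TEK, the angiopoietin receptor, rose and FLT1 had a log2 fold change of -0.42 (adjusted p = 0.327); the same 2 were called when adjusted over the list alone. This list passed camera as well (adjusted p = 0.0163; adjusted p = 0.172 with an estimated correlation), though not when genes with at least 20 counts in total were tested.

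**Figure D3:**
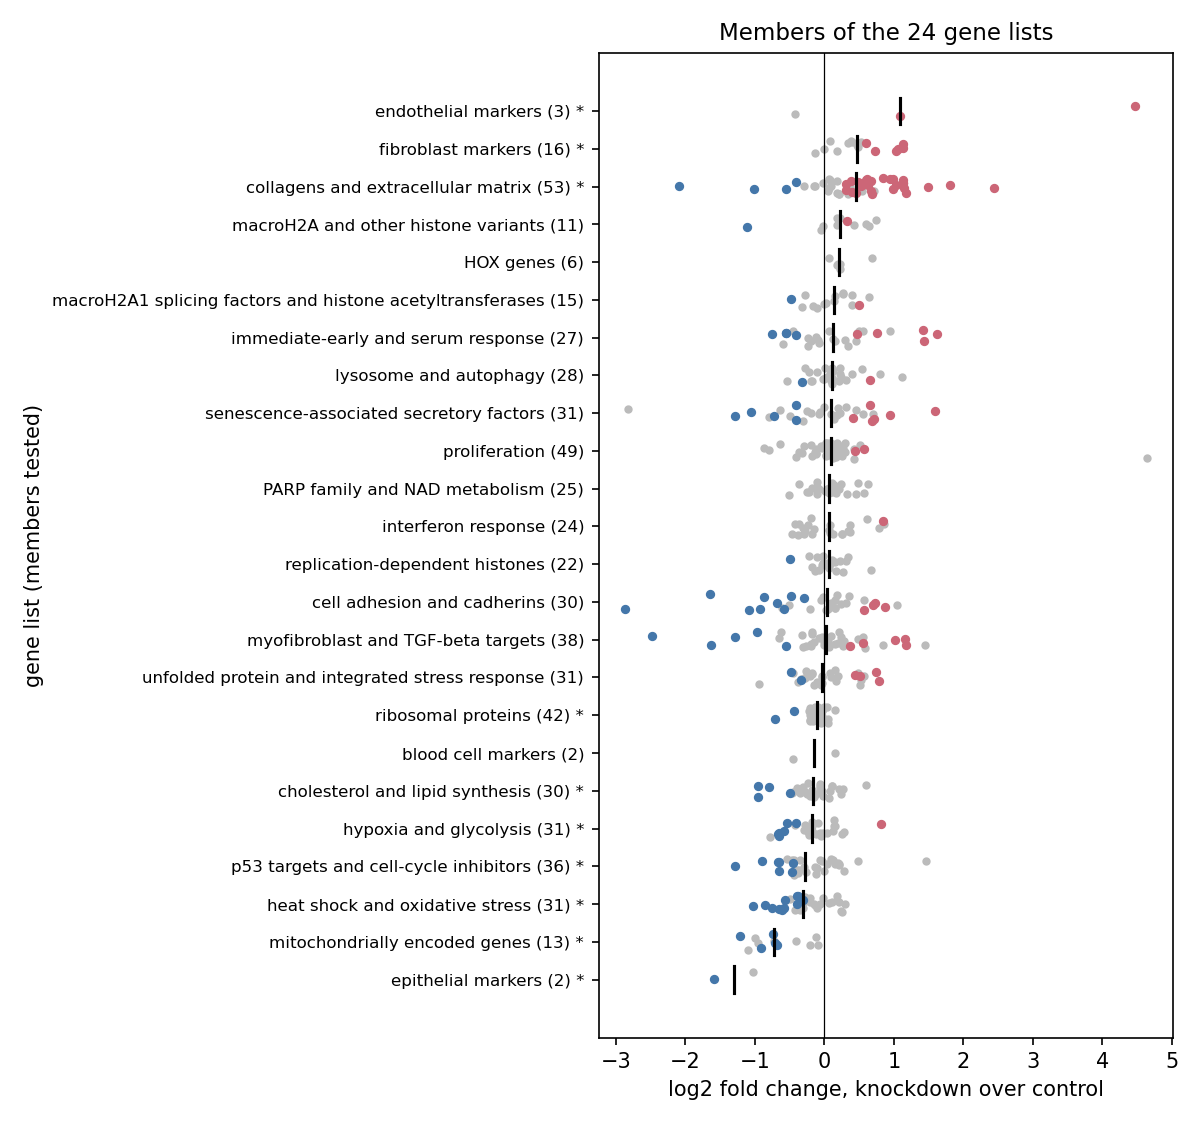
Log2 fold change, knockdown over control, of every tested member of the 24 gene lists; red points rose, blue points fell, grey points did not pass an adjusted p of 0.05, and black lines are list medians. Stars mark the 10 lists past camera with its preset correlation, such as the matrix list with 29 members higher and 4 lower; none passed with an estimated correlation (lowest adjusted p = 0.151).

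In several lists of stress and metabolic genes, more members fell than rose. Of 31 tested genes of the heat shock and oxidative stress list, 11 fell and none rose (14 fell and 1 rose when adjusted over the list alone). The chaperone HSP90AA1 fell from 496 ± 5.53 to 324 ± 16.6 CPM, the co-chaperone DNAJB4 from 71.0 ± 8.80 to 34.8 ± 3.86, the metallothionein MT2A from 27.3 ± 1.64 to 15.1 ± 0.363, and the peroxiredoxin PRDX6 from 151 ± 5.89 to 96.0 ± 7.14 (n = 3 per group, edgeR adjusted p at most 0.00583). All 13 mitochondrially encoded genes had negative fold changes, and 5 passed (8 were called when adjusted over the list alone): MT-ND4L, MT-CO3, MT-ND5, MT-CYB and MT-ATP8. MT-ND4L, a subunit of complex I, was 1.89-fold lower and MT-CO3, a subunit of cytochrome c oxidase, 1.68-fold lower. MT-ND5 and MT-CYB each lost their call in 7 of 18 alternative settings, and MT-CO3 in 4. Reads without a unique alignment were not counted, and their share was 68.1% in the control and 65.7% in the knockdown. Whether this moved the mitochondrial list was not tested. The heat shock list passed camera (adjusted p = 0.000184; adjusted p = 0.151 with an estimated correlation), as did the mitochondrial list (adjusted p = 3.32e-06; adjusted p = 0.151 with an estimated correlation). With 1 library left out, 6 heat shock genes were called whichever library it was, and 1 mitochondrial gene without control replicate 1, control replicate 2 or knockdown replicate 3 and 3 without any other.

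Of 36 p53 targets and cell-cycle inhibitors, 7 fell and none rose (10 fell and 1 rose when adjusted over the list alone). Among them were RRM2B, MDM2, CDKN2B, CDKN1A, POLH and EDA2R; RRM2B, a ribonucleotide reductase subunit, fell from 79.8 ± 2.04 to 50.1 ± 6.50 CPM (n = 3 per group, edgeR adjusted p = 0.0125), and MDM2, which targets p53 for degradation, was 1.39-fold lower. RRM2B, MDM2 and CDKN2B lost their calls in 2, 6 and 5 of 18 alternative settings. The list passed camera (adjusted p = 0.00492; adjusted p = 0.151 with an estimated correlation). Of 30 genes of cholesterol and lipid synthesis, 4 fell and none rose (7 fell and 1 rose when adjusted over the list alone). STARD4, which carries sterols, MSMO1 and IDI1 were among them, with log2 fold changes of -0.96, -0.79 and -0.49 (list adjusted p = 0.00719; adjusted p = 0.151 with an estimated correlation). IDI1 lost its call in 15 of 18 alternative settings. Of 31 genes of hypoxia and glycolysis, 6 fell, among them the glucose transporter SLC2A3, LDHA and PDK1 at 1.58-fold, 1.45-fold and 1.58-fold lower, and 1 rose, EPAS1, which encodes a hypoxia-inducible factor, at 1.76-fold (12 were called when adjusted over the list alone; list adjusted p = 0.0163, and adjusted p = 0.316 with an estimated correlation).

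Of 42 ribosomal protein genes, 38 had negative fold changes with a median log2 of -0.10, and RPL28 and RPS16 fell (2 were called when adjusted over the list alone). RPL28 lost its call in 6 of 18 alternative settings and RPS16 in 5. Reads without a unique alignment were not counted, and their share was 68.1% in the control and 65.7% in the knockdown. Whether this moved the ribosomal protein list was not tested. The list passed camera (adjusted p = 0.0163; adjusted p = 0.261 with an estimated correlation), but not without knockdown replicate 2 or with the trend on GC content and length removed. Only 2 of 22 epithelial markers were expressed enough to test: KRT18, a keratin, was 3.01-fold lower, and KRT8 had a log2 fold change of -1.02 (adjusted p = 0.0786; both were called when adjusted over the list alone). That list passed camera (adjusted p = 0.00667; adjusted p = 0.151 with an estimated correlation), though not when every gene with 1 count was tested, where its median log2 fold change was 0.92 instead of -1.31 (adjusted p = 0.436). Of the blood cell markers, CD4 and CD68 were tested and neither passed, and neither was called when adjusted over the list alone (list adjusted p = 0.721).

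Other lists held called genes that went both ways and did not pass camera. Of 31 tested senescence-associated secretory factors, 6 rose and 5 fell (18 were called when adjusted over the list alone; list adjusted p = 0.979): HGF, hepatocyte growth factor, rose 1.92-fold, while the collagenase MMP1 and FGF2 were 2.08-fold and 1.65-fold lower. Of 38 myofibroblast and TGF-beta target genes, 5 rose and 5 fell (18 were called when adjusted over the list alone; list adjusted p = 0.979): TGFBI and ID3 rose 2.27-fold and 2.23-fold, and INHBA was 1.96-fold lower. Of 27 immediate-early genes, 5 rose, among them NR4A1 at 3.09-fold and FOS at 2.69-fold, and 4 fell, among them FOSL1 and ETV5 (14 were called when adjusted over the list alone; list adjusted p = 0.513). Of 30 cell adhesion genes, 4 rose, PCDH18 at 1.83-fold among them, and 9 fell, ITGA6 at 2.12-fold and CADM1 at 1.61-fold lower among them (18 were called when adjusted over the list alone; list adjusted p = 0.466). Of 31 genes of the unfolded protein and integrated stress responses, VLDLR, PHGDH, DDIT4 and PSAT1 rose and HSPA5 and CANX fell (15 were called when adjusted over the list alone, list adjusted p = 0.979). HSPA5 lost its call in 6 of 18 alternative settings and DDIT4 in 3. The median and the mean differed in sign for the secretory, TGF-beta, cell adhesion and unfolded protein lists; camera took the direction of the mean for all of them but the TGF-beta list, where the mean was -0.0086 and camera gave up.

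The lists tied to macroH2A1 itself held 0 to 2 called genes each, where 8.21% of all genes tested were called. Whether their share differs from that was not tested. In the list of 11 histone variants, MACROH2A1 fell and H3-3B, a gene of the variant H3.3, rose 1.25-fold (2 were called when adjusted over the list alone; list adjusted p = 0.243), and H3-3B lost its call in 10 of 18 alternative settings. H1-1 fell among 22 tested replication-dependent histones (2 were called when adjusted over the list alone; list adjusted p = 0.655). H1-1 lost its call in 12 of 18 alternative settings. None of 25 genes of the PARP family and NAD metabolism passed with edgeR, over all genes tested or when adjusted over the list alone (list adjusted p = 0.721). PARP1, a member of that family, had a log2 fold change of -0.26 (SE 0.08, edgeR adjusted p = 0.0925). Of 15 splicing factors and acetyltransferases linked to macroH2A1, KAT6B rose 1.41-fold and QKI, an RNA-binding protein that acts in its splicing, was 1.40-fold lower (2 were called when adjusted over the list alone; list adjusted p = 0.517). KAT6B lost its call in 4 of 18 alternative settings and QKI in 6. When edgeR tested only genes of the authors' deposited table, it called 3, 6, 2 and 5 genes of these lists, in the same order.

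Of 49 proliferation genes, KIF20A and BIRC5 rose and none fell (none was called when adjusted over the list alone; list adjusted p = 0.486). They lost their calls in 7 and 11 of 18 alternative settings. IFIT1 rose among 24 interferon response genes (none was called when adjusted over the list alone; list adjusted p = 0.955). It lost its call in 10 of 18 alternative settings. GABARAPL1, of autophagosome formation, rose 1.58-fold among 28 lysosome and autophagy genes (5 were called when adjusted over the list alone; list adjusted p = 0.311). All 6 tested HOX genes had positive fold changes and none passed, HOXA5 with a log2 fold change of 0.68 (edgeR adjusted p = 0.0561; 1 was called when adjusted over the list alone; list adjusted p = 0.152). Of the 24 lists, 10 passed camera with the preset correlation and none with an estimated one, where the lowest adjusted p was 0.151; 14 passed fry, which tests whether the genes of a list move one way and makes no comparison with other genes.

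The authors' deposited table of the same comparison covers 11638 genes, protein-coding by its name, and calls 635 higher and 765 lower in the knockdown. Of its genes, 10478 were also tested with edgeR; 942 were called in both with the same direction and 0 with opposite directions. A further 441 were called in the authors' deposited table alone and 62 with edgeR alone. The authors' deposited table gives MACROH2A1 a log2 fold change of -1.10 and COL14A1 one of 2.45. With 1 library left out, the number shared with the authors' deposited table was 394, 394 and 501 without control replicate 1, 2 and 3 and 473, 480 and 445 without knockdown replicate 1, 2 and 3.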

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

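No test of this part was chosen before the result was seen. The share of reads outside annotated features was 8.94% ± 0.555 in the control libraries and 10.8% ± 0.388 in the knockdown libraries (SD, n = 3 per group), 1.90 percentage points more, with no overlap between groups (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 can give). It drew attention as a signal in lines of the count files that no gene comparison uses. The share without a unique alignment was lower in the knockdown, 65.7% ± 1.15 against 68.1% ± 0.619 (n = 3 per group, exact permutation p = 0.1), also without overlap.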

How the results depend on the processing

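The robust prior and the GC and length offset were chosen after the data were seen; the other alternatives were fixed before. MACROH2A1 kept its direction and call in every alternative run, with log2 fold changes from -1.16 to -1.07. Of 89 other called named genes, 50 kept the call in every alternative and 36 lost it without at least 1 library; none of these reversed. The reversed value was that of CD4, which was not called: 0.15 in all libraries, -0.078 without control replicate 1 and 0.334 without control replicate 3; the cause was not tested.

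Against 1104 called genes (524 higher, 580 lower), testing only genes of the authors' deposited table called 2060 (1014 higher, 1046 lower). The gene sets differ: that table holds protein-coding genes by its name, whereas the main fit had 13445 genes, 10437 of them protein-coding. The cause of the higher number was not tested. Leaving out 1 library called 427 to 564 (225 to 303 higher, 198 to 262 lower) and shared 394 to 501 calls with the authors' deposited table, against 942; these fits hold fewer samples. A threshold of 0.01 called 317 (173 higher, 144 lower), 0.1 called 1881 (908 higher, 973 lower), and 0.05 with at least a 2-fold change called 271 (178 higher, 93 lower), by construction. DESeq2 called 1242, limma-voom 1219 and the robust prior 1549.

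The replicate numbers did not pair the libraries: deviations of same-numbered libraries from their group means correlated at -0.025, -0.018 and -0.173 across genes, and no library correlated best with its own number. With the replicate block, 416 genes were called (230 higher, 186 lower), 378 of them shared with the authors' deposited table; the block leaves fewer residual degrees of freedom.

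The number of gene lists past the threshold was 9 to 10 in the other camera fits, 14 by fry and 0 with an estimated correlation. For the p53, cholesterol, epithelial and endothelial lists the estimates were -0.024, 0.0090, -0.37 and -0.40. These lie below the preset 0.01, so a higher correlation cannot be why these lists lost their call. For the other lists that lost it, the estimates were 0.026 to 0.257. What else changed the results was not tested. Over the single lists, 414 results kept their side of the threshold, 14 lost the call and 4 gained it. With 1 library left out, the number of members called, not always the same genes, was 2 to 6 for p53 targets against 7 with all libraries, 2 to 4 for cholesterol genes against 4, 3 to 5 for hypoxia genes against 7 and 5 to 7 for fibroblast markers against 6. In the same fits it was 6 to 9 for secretory factors against 11, 4 to 5 for immediate-early genes against 9, 7 to 11 for adhesion genes against 13 and 2 to 4 for unfolded protein and stress response genes against 6. Of lists with 2 called genes, the endothelial list had 2, the histone variant and lysosome lists 1, and the proliferation, splicing factor and ribosomal protein lists 0 to 1. The interferon response and replication-dependent histone lists, with 1 called gene each, had none. More members were called when only genes of the authors' deposited table were tested: 20 secretory factors, 15 immediate-early, 21 adhesion, 20 TGF-beta, 13 unfolded protein, 11 p53, 39 matrix, 14 heat shock, 14 hypoxia, 9 cholesterol and 11 fibroblast genes. The median of the epithelial list was 0.92 instead of -1.31 with no filter beyond 1 count; the cause was not tested. Medians of the replication-dependent histone, interferon, TGF-beta, unfolded protein and blood cell lists, none past camera, also changed sign in some alternatives. With 3 libraries per group at the depth and spread of these data, edgeR recovered 1.49% of simulated changes of 0.5 on the log2 scale. Depth was not varied by itself. The simulation gave 94 calls against 1104 in the data, and the p that passes the adjustment depends on this number. The share is therefore not the recovery in these data.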

Other observations

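Tests on endothelial cells, on YAP and TAZ targets, on neighbouring genes within expression bins or without similar symbols, and the list of alveolar fibroblast markers were chosen after results had been seen; the other tests were set before the values they measure. Genes outside the lists, picked here after their values were seen, also changed. BMP4, a growth factor, rose from 13.6 ± 1.87 to 56.9 ± 1.66 CPM, ADH1B, an alcohol dehydrogenase, from 8.24 ± 1.77 to 46.3 ± 0.595 CPM, and MFAP4, a protein of elastic fibres, from 14.3 ± 1.47 to 48.7 ± 5.03 CPM (n = 3 per group, edgeR adjusted p at most 0.000844). IL1R1, the interleukin-1 receptor, rose 2.47-fold. HMGA2, a chromatin protein of proliferating and embryonic cells, fell from 127 ± 5.23 to 46.6 ± 1.85 CPM, and CCND1, cyclin D1, was 1.83-fold lower (edgeR adjusted p = 0.000566 and 0.00144). PDE4D, a phosphodiesterase, rose 2.75-fold, and GUCY1A1 and GUCY1B1, which encode both subunits of soluble guanylate cyclase, rose 2.97-fold and 2.75-fold.

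The real grouping called 1104 genes and 10 lists, and the highest of the other splits of the 6 libraries called 1 gene and 3 lists. Only 1 of 10 splits, the real one, gave results as large, and 10 splits are too few for a share under 0.05.

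The rise of matrix genes was set against technical explanations. With a per-library trend on GC content and transcript length removed, the median log2 fold change of the list was 0.39 instead of 0.45, and 27 instead of 29 members rose. This argues against that trend as the whole cause. A test under other scalings decides nothing: a scaling moves all genes alike, so the lowest difference from the median of all genes, 0.443, was bound to stay near that of the first fit. A response to the hairpin against macroH2A1 is a hypothesis that stays open, and so is an effect of the hairpin on other targets, since no other hairpin was analysed here. A difference in RNA or library quality was not tested and stays open as well, as the groups did not overlap in the share of reads outside annotated features (8.94% in the control, 10.8% in the knockdown) or without a unique alignment (68.1% and 65.7%).

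The lower levels of heat shock and mitochondrial genes were weighed in the same way. With the GC and length trend removed, the median over both lists was -0.323, against -0.359 before. After that removal, 13 instead of 16 members fell and 1 instead of 0 rose. A trend of this kind is therefore argued against as the whole cause, while a difference in RNA or library quality, with the same read shares, was not tested and stays open.

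The rise of KDR and TEK was set against endothelial cells in the knockdown cultures. In the first test, the summed CPM of PECAM1, CDH5 and VWF had to stay under 10% of that of KDR in every knockdown library to count against them, and it did not: the shares were 5.88%, 6.06% and 14.8%, the last made up of VWF alone, which had 4 counts there and 8 in all knockdown libraries against 17 in the control. A second test was added only after the first missed its bound, with these counts in view: PECAM1 and CDH5 together had 1 count in the knockdown libraries, whose upper 95% Poisson limit is 5.32% of the rise of KDR. No knockdown library had more than 1 count of any of PECAM1, CDH5, TIE1, ESAM, CLDN5, EMCN, ERG, ROBO4, SOX17 and SOX18; EGFL7 had 3, 1 and 8 counts there and 5, 4 and 2 in the control. TEK went from 62.3 to 132 CPM and FLT1 from 6.40 ± 1.17 to 4.83 ± 0.861 CPM (n = 3 per group). Endothelial cells would bring these transcripts too, so they are argued against as the source of the rise; its cause in the fibroblasts was not tested.

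One hypothesis was that genes called in the same direction lie next to each other. Among 10437 tested protein-coding genes in chromosome order, 91 neighbouring pairs were called in the same direction, against 48.7 on average when calls were shuffled 10000 times (permutation p = 1e-04, the smallest these shuffles can give). Pairs called in opposite directions numbered 41, against 48.0 shuffled (permutation p = 0.877). The excess held when calls were shuffled within 20 bins of expression (51.1 on average) and without pairs whose symbols share their first 3 characters (83 against 46.5), each with permutation p = 1e-04. Pairs such as LUM and DCN, COL3A1 and COL5A2, and GUCY1A1 and GUCY1B1 are related genes, and shared regulation of neighbours in any condition may give the same excess.

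A second hypothesis was that targets of the growth regulators YAP and TAZ fall together. Of 22 targets tested, 6 fell and 1 rose, with a median log2 fold change of -0.29 (camera p = 0.00626, and p = 0.108 with an estimated correlation). ANKRD1 fell by 2.47 on the log2 scale and CRIM1 by 0.87, while CCN2 rose by 0.56; several of these values had been seen before the test. Another was that markers of alveolar fibroblasts of the lung rise together, on a list drawn up once the highest genes were known. Of 10 tested, WNT2, SCN7A, RARRES2, LIMCH1 and FGFR4 rose and none fell, with a median of 0.60 (camera p = 0.00131, and p = 0.0880 with an estimated correlation). The result therefore depends on the setting of camera and does not decide the question.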
